A study of Mus musculus with 6 samples.

How the data were processed

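Total RNA of sorted bone marrow multipotent progenitors was labelled from 100 ng and hybridised to Affymetrix MoGene 1.0 ST arrays, per the labels' protocols. The labels give 3 biological replicates of each genotype, each pooled from several mice, and the groups and replicate numbers come from the sample titles. Each array is a separate pool, so the p-values of single features measure the spread between pools. The authors deposited 1 table of log2 expression values with 35557 features, normalized by RMA per the series text. Partek 6.0 is named in the submitters' processing notes, and limma is named in the series text for the authors' own tests. The log2 scale was inferred from the range of the deposited values, 2.93 to 14.78 over the tested features. The RMA background and summary settings, the scan dates and the genome build are not given in the sources used here. RMA forces arrays to a common distribution before probes are combined, so a difference in total RNA per cell is not measurable, and differences in width that remain after summarising are part of the deposited values.

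Features were named through the platform's probe-to-gene table, with symbols updated through Entrez identifiers in the GRCm38.p6 gene table. The table gives 1 gene symbol for 21789 features, several for 1621 and none for 12147. Of the first, 21698 matched the gene table, and the 91 others keep the platform's symbol. The 23410 features with at least 1 symbol were tested, and those with several were counted and left unnamed. Where several features carry 1 gene (998 genes), the feature with the highest mean over all 6 arrays stands for it, which leaves 19939 genes for the lists. No coordinates are printed, and chromosomes and neighbouring genes come from that gene table.

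The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without trend, two-sided), with Benjamini-Hochberg adjustment over all tested features and a threshold of 0.05. A looser count used an unadjusted p under 0.01 with at least 1.5-fold. The 39 gene lists were tested with camera (inter-gene correlation preset to 0.01, adjusted over the lists), with camera using an estimated correlation and with fry. Single members were also adjusted over the list alone. The genes flanking Lxn were compared with all other genes by Fisher's exact test, leaving out Lxn and the overlapping Gfm1. That test counts genes, and camera with the preset correlation sets list members against other genes. Neither p-value therefore measures the spread between pools. After the data were seen, each called list was set against 10000 random lists matched on mean level in 20 bins. In simulated arrays with the means and spreads of this comparison (23410 features, 3 arrays each), the fit recovered 59.0% of 200 features changed 1.5-fold, 93.0% of those changed 2-fold and 100% of those changed 4-fold, with 4.4% false calls. Simulated features varied independently, and all changes were planted at once. These shares therefore need not hold in the real arrays, whose features vary together.

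The design, the tests, the gene lists, the naming rule and the first set of alternatives were fixed before the data were examined. Lxn, Gfm1, Thbs1, Kit, Ly6a, Flt3 and Cd34 are always named. Up to 12 passing genes per direction were to be named by size of change, and where fewer than 10 passed, the list was filled to 10 with the genes of smallest unadjusted p among those with a log2 change of at least 0.5 and no overlap between groups, which are said not to pass. Symbols of predicted genes, clones, olfactory and vomeronasal receptors and small RNAs were counted and not named. For each list, up to 4 members passing over all features or over the list alone are named, or else 2 to 4 with the largest moderated statistics, and lists given by their adjusted p alone have no member named. Xist and the Y-linked genes were a list fixed in advance. Genes named as moving with the Y-linked signal, and single features under alternatives, were chosen after their values were seen.

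The alternatives were the replicate number as a block, each array left out in turn, quantile normalization of the tested features, centring each array on its median, features above the median level only, eBayes with trend and robust settings, array weights, all rows of the value table, an equal-variance two-sample test, other thresholds, genes counted once, the mean of a gene's features and a 10 Mb window around Lxn. Autosomal single-gene features only, the comparison without knockout-labelled arrays 1 and 3, and quantile normalization over 1 feature per gene, were added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.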

Results

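RNA of multipotent progenitors was profiled on 6 whole-transcript mouse arrays, 3 from wild-type mice and 3 from mice carrying a deletion of exons 2 to 4 of latexin (Lxn), which encodes an inhibitor of carboxypeptidases. The cells were sorted from bone marrow as lineage-negative, Sca-1 and c-Kit positive cells that were also positive for CD34 and for the receptor that the series text writes as Flt2. The same text names long-term hematopoietic stem cells in its title and where it gives the cell number, so the population is taken here from the sample labels and the sort gate. Each sample held about 100000 cells pooled from 10 to 20 C57BL/6 mice of 8 to 12 weeks, and the labels describe all donors as female. The comparison asks which genes differ in these progenitors when latexin is absent. The values are log2 expression values, of which 23410 features with at least 1 gene symbol were tested, and the 6 arrays limit the precision of every value below. Differences are given as arrays labelled Lxn knockout minus wild type, as log2 change with its standard error (SE) from limma, and levels are group means ± SD with n = 3 per group.

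The deleted gene did not separate the groups. Lxn had a log2 value of 8.56, 8.70 and 8.58 in the 3 wild-type arrays and 8.03, 8.53 and 8.61 in arrays 1, 2 and 3 labelled Lxn knockout. The change of -0.22 (SE 0.15) had an adjusted p of 0.459. Which exons the feature's probes cover is not given in the sources used here, and a probe outside exons 2 to 4 would check nothing. Probes inside them should read lower, yet array 3 lay inside the wild-type range and array 2 just below it. Lxn therefore does not check the genotype of any array, and the groups are named below by their labels. Gfm1, a mitochondrial translation factor gene that overlaps Lxn, was 9.10 ± 0.10 in wild type and 9.50 ± 0.26 in the arrays labelled Lxn knockout, a change of 0.40 (SE 0.13) with an adjusted p of 0.340. All 3 knockout-labelled values of Gfm1 lay above all 3 wild-type values.

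Sex-linked genes split the arrays labelled Lxn knockout. Xist, the RNA that silences 1 X chromosome in female cells, was 13.19 ± 0.05 in wild type and 13.17 in knockout-labelled array 2, but 6.86 and 5.85 in arrays 1 and 3. The Y-linked genes ran the other way. Eif2s3y, a translation initiation factor gene, was 8.57 and 9.36 in arrays 1 and 3, against 3.83 in array 2 and 3.84 ± 0.15 in wild type. Kdm5d was 7.88 and 8.56 in arrays 1 and 3 and at most 5.38 in the other 4, and Uty was 8.55 and 9.43 in arrays 1 and 3 and 4.63 in array 2. Both encode histone demethylases or their relatives, and their wild-type means were 5.16 ± 0.19 and 4.82 ± 0.31. These 4 measured members of the list of sex-linked check genes passed with adjustment over the list alone (adjusted p of 0.0253 each in limma) and not over all features (smallest adjusted p 0.340), and the list itself missed the camera threshold (adjusted p 0.0527).

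The same 2 arrays stood apart on the first axis of the whole profile. The first principal component held 48.1% of the variance and placed arrays 1 and 3 labelled Lxn knockout at 29.5 and 27.8, array 2 at -8.1 and the wild-type arrays at -13.6, -20.9 and -14.8. The second (23.6%) placed arrays 2 and 3 at -22.7 and -14.6, below the wild-type arrays at 4.4, 12.0 and 1.9, and array 1 above them. Array 2 correlated with the 3 wild-type arrays at 0.9946, 0.9919 and 0.9947 across features, and with arrays 1 and 3 at 0.9849 and 0.9902. Features are not independent replicates, and these values describe similarity only. No 2 arrays shared more than 14 identical values, so all 6 were kept as separate samples.

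**Figure D1:**
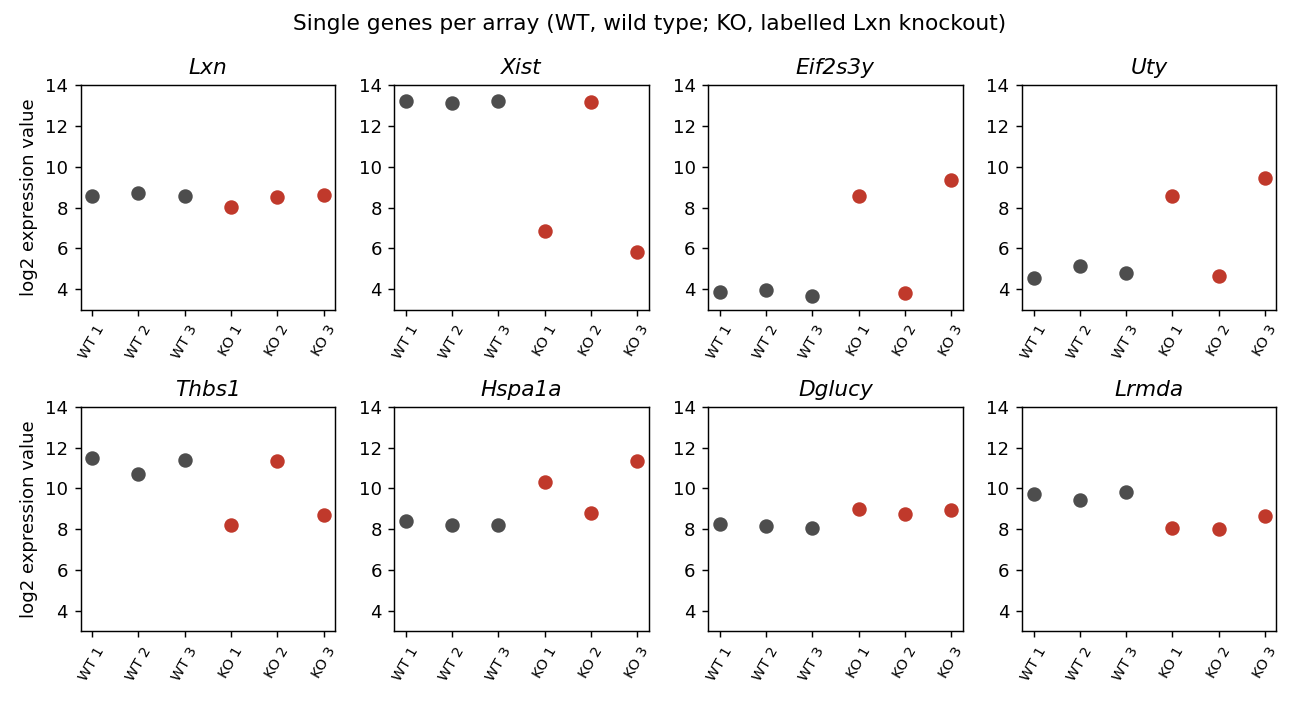
Log2 expression values (vertical axis) of 8 genes in each of the 6 arrays (horizontal axis, 1 point per array, grey for wild type, red for the label Lxn knockout). Xist lies at 6.86 and 5.85 in knockout-labelled arrays 1 and 3 and at 13.17 in array 2, whereas Lrmda lies at or below 8.65 in all 3 of them and at 9.43 or above in wild type.

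Thbs1, which encodes the matrix protein thrombospondin 1, was lower in 2 of the 3 knockout-labelled arrays. It was 11.47, 10.70 and 11.41 in wild type, and 8.20, 11.34 and 8.69 in arrays 1, 2 and 3 labelled Lxn knockout. The change of -1.78 (SE 0.68), a 3.44-fold lower mean, had an adjusted p of 0.340 and did not pass. Without array 2 it was -2.75 (SE 0.22) with an adjusted p of 3.9e-05. The 2 arrays with low Thbs1 were those with Y-linked signal.

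No feature passed an adjusted p of 0.05 in limma. The smallest adjusted p was 0.340, while 3346 features had an unadjusted p under 0.05, 14.3% of those tested, where chance gives about 1170. Of these, 1185 were higher and 2161 lower in the arrays labelled Lxn knockout. The count went from 1628 without knockout-labelled array 3 to 5541 without array 1, and it was 1904 without wild-type array 2 and 1812 after the arrays were quantile-normalized again. An equal-variance two-sample test also passed 0 features after adjustment and had 2588 at an unadjusted p under 0.05. The groups did not overlap in 21.6% of features, against 10% by chance for 3 arrays against 3. At an unadjusted p under 0.01 and at least 1.5-fold there were 44 features, 23 higher and 21 lower, of which 9 carry several gene symbols and are left unnamed. Without knockout-labelled array 2, 145 features passed the adjusted threshold, 113 higher and 32 lower. Of these, 86 carry at least 1 gene on the Y chromosome (22 of a single gene, 64 of several genes), and 50 are single-gene autosomal features.

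Among the 10 genes named by the rule as higher in all 3 knockout-labelled arrays, none passing the threshold (adjusted p 0.340 for each), 2 encode lysosomal or matrix-degrading enzymes. Lgmn, the cysteine protease legumain, was 8.06 ± 0.07 in wild type and 8.67 ± 0.12 in the arrays labelled Lxn knockout (log2 change 0.61, SE 0.10), and Hpse, heparanase, had a log2 change of 0.58 (SE 0.10). Dglucy, a mitochondrial enzyme gene, had the smallest p of the higher genes with a change of 0.71 (SE 0.10), and both Dglucy and Lgmn lie on chromosome 12. Immune receptor and signalling genes in this set were Ccr2, the receptor of the chemokine CCL2 (0.75, SE 0.16), Card9 (0.60, SE 0.12), Milr1 (0.61, SE 0.135) and Clec2i (0.53, SE 0.12). The others were B4galt4, a galactosyltransferase gene (0.55, SE 0.10), Kmo, of tryptophan breakdown (0.51, SE 0.11), and Ppp3cc, a calcineurin subunit gene (0.51, SE 0.10). In all, 31 genes met the naming conditions for higher values. Without knockout-labelled array 2, Dglucy, Lgmn and Card9 passed (adjusted p of 0.00699, 0.0182 and 0.0237).

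Lrmda, a gene of melanocyte differentiation, had the lowest p of all features (2.5e-05). It was 9.66 ± 0.21 in wild type and 8.23 ± 0.37 in the arrays labelled Lxn knockout, a log2 change of -1.43 (SE 0.18), with 8.00 in array 2, which had no Y-linked signal. It did not pass (adjusted p 0.340), as was the case for every other gene in this paragraph. Entpd4, a Golgi or lysosomal nucleotidase gene, was 11.16 ± 0.03 in wild type and 10.64 ± 0.06 in the arrays labelled Lxn knockout (-0.52, SE 0.08). Synb, which encodes the placental fusion protein syncytin B, had a change of -0.51 (SE 0.12). It is next to Entpd4 in the order of measured, named genes on chromosome 14, where Lrmda and Ppp3cc also lie. Also lower were the X-linked gene Kir3dl1 (-0.82, SE 0.12), Gdf3 of the TGF-beta family (-0.63, SE 0.13) and the acute-phase gene Saa1 (-0.62, SE 0.14). Saa1 was dim, at 4.57 ± 0.18 in wild type and 3.95 ± 0.24 in the arrays labelled Lxn knockout. That is in the lowest decile of mean level, where the median change was -0.107. The remaining lower genes were Tmem121b (-0.62, SE 0.16), Krtap5-3 (-0.59, SE 0.13), the red-cell pyruvate kinase gene Pklr (-0.58, SE 0.15) and the transglutaminase gene Tgm2 (-0.54, SE 0.12). In all, 28 genes met the naming conditions for lower values. Without knockout-labelled array 2, Lrmda, Kir3dl1, Gdf3, Saa1 and Tmem121b passed (adjusted p of 0.00499, 0.00323, 0.0395, 0.0277 and 0.0432), and without array 3 Lrmda did (0.0441).

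Gene lists of growth and protein folding rose as sets in the arrays labelled Lxn knockout by camera. All 29 measured ribosome biogenesis and Myc-linked genes had higher means, with a median log2 change of 0.275 (camera adjusted p of 4.0e-12, adjusted p = 0.544 with an estimated correlation). Examples are the nucleolar factor genes Utp20 (0.38, SE 0.13), Tsr1 (0.29, SE 0.11), Gnl3 (0.28, SE 0.11) and Nop16 (0.30, SE 0.12). All 37 G1/S and replication genes were likewise higher, at a median of 0.189 (adjusted p of 1.1e-11, adjusted p = 0.544 with an estimated correlation), among them Gins3 (0.33, SE 0.09), Rrm2 (0.39, SE 0.12), Orc1 (0.45, SE 0.14) and Rfc4 (0.31, SE 0.10). Of 37 G2/M genes 35 were higher (median 0.122, adjusted p of 2.9e-06, adjusted p = 0.544 with an estimated correlation), with Bub1 at 0.26 (SE 0.11) and Hmmr at 0.34 (SE 0.16). The G2/M median lay inside the central 95% of random lists matched on mean level (percentile 94.9). Of 64 oxidative phosphorylation genes 59 were higher (median 0.141, adjusted p of 1.0e-09, adjusted p = 0.544 with an estimated correlation), with Ndufb6 at 0.47 (SE 0.17) and Sdhd at 0.26 (SE 0.10). Relative to the wild-type mean, the ribosome biogenesis median was 0.51, 0.13 and 0.19 in arrays 1, 2 and 3 labelled Lxn knockout, and 0.15, -0.03 and -0.06 in the wild-type arrays. None of these members passed over all features or over the list alone. Without knockout-labelled array 1 the medians were 0.170 for ribosome biogenesis, 0.101 for G1/S and 0.073 for oxidative phosphorylation genes, and without wild-type array 2 that of G2/M genes was 0.062, all still passing camera.

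Heat shock and protein folding genes had the largest median change among the called lists that were higher. Of 18 measured members 16 were higher, at a median of 0.308 (camera adjusted p of 4.9e-09, adjusted p = 0.544 with an estimated correlation), and 6 rose with adjustment over the list alone, 0 over all features. They include Chordc1, an HSP90 cochaperone gene (0.59, SE 0.14), Hspa1a, the inducible HSP70 (1.88, SE 0.50), the cochaperone gene Bag3 (0.41, SE 0.12) and Hsph1 (0.85, SE 0.25), each with a list-alone adjusted p of 0.0380. Hspa1a was 10.32 and 11.33 in arrays 1 and 3, against 8.80 in array 2 and 8.27 ± 0.12 in wild type, and its level thus moved with the Y-linked signal. Endoplasmic reticulum stress genes rose (21 of 26 higher, median 0.144, adjusted p of 9.0e-05, adjusted p = 0.544 with an estimated correlation), with the chaperone genes Pdia4 at 0.32 (SE 0.11), Hsp90b1 at 0.28 (SE 0.11) and Creld2 at 0.45 (SE 0.19). Creld2 was 10.91 and 10.68 in arrays 1 and 3, against 10.07 in array 2 and 10.11 ± 0.10 in wild type, with a change of 0.27 without array 1, and Creld2, Hspa1a and Hsph1 passed without array 2 (0.69, 2.56 and 1.16, adjusted p of 0.0316, 1.1e-04 and 0.00699). Of the endoplasmic reticulum list, Atf3 also passed as higher without array 2 (1.18, adjusted p of 0.0131). Ern1 of that list passed there in the other direction (-0.84, adjusted p of 0.0302). Immediate early and dissociation stress genes rose as well (23 of 26 higher, median 0.154, adjusted p of 6.7e-04, adjusted p = 0.637 with an estimated correlation), including Fos (0.44, SE 0.22) and Socs3 (0.28, SE 0.15). Their median relative to wild type was 0.33 and 0.45 in arrays 1 and 3 and -0.27 in array 2. The immediate early list lost its call without array 1 (median 0.083, adjusted p of 0.0551) or array 3 (0.006, adjusted p of 0.364), and its median was 0.390 without array 2, where that of the endoplasmic reticulum list was 0.230.

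Anti-apoptotic genes rose as a set (20 of 22 higher, median 0.121, camera adjusted p of 2.9e-04, adjusted p = 0.439 with an estimated correlation). The members with the largest statistics were Bag3 and Bag1 (0.28, SE 0.11). Pro-apoptotic genes missed the threshold (adjusted p 0.0752) at a median of 0.056, with Bak1 at 0.27 (SE 0.11), Bik at -0.26 (SE 0.11) and Hrk at -0.19 (SE 0.08). The difference between these 2 lists was not tested. Without knockout-labelled array 3 the anti-apoptotic median was 0.074, and without array 1 the glycolysis list described next had a median of 0.036 and lost its call (adjusted p of 0.0938). Glycolysis and hypoxia genes rose (16 of 25 higher, median 0.095, adjusted p of 0.0126, adjusted p = 0.544 with an estimated correlation), with the oxygen sensor gene Egln3 at 0.35 (SE 0.09) and the hypoxia-induced growth factor gene Vegfa at -0.39 (SE 0.12). Cytoplasmic ribosomal protein genes had a median of 0.028 over 55 members (adjusted p of 0.0373, adjusted p = 0.720 with an estimated correlation), which turned to -0.034 when the arrays were quantile-normalized again. Rpl14 was at 0.39 (SE 0.12) and Rpl12 at 0.20 (SE 0.09). Cholesterol and fatty acid synthesis genes had a median of 0.052 over 25 members (adjusted p of 0.0400, adjusted p = 0.720 with an estimated correlation), which likewise turned to -0.018. Msmo1, a sterol oxidase gene, was at 0.16 (SE 0.09), and Acaca, which encodes an acetyl-CoA carboxylase, at 0.21 (SE 0.12). The anti-apoptotic, glycolysis and cholesterol medians lay at percentiles 95.2, 87.0 and 37.6 of random lists matched on mean level. None of them left the central 95% of those lists.

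Erythroid, megakaryocyte, mast cell and stem cell genes fell as sets. Of 20 measured erythroid genes 18 were lower, at a median of -0.304 (camera adjusted p of 0.00142, adjusted p = 0.552 with an estimated correlation), including the blood group gene Ermap (-0.54, SE 0.19), the water channel gene Aqp1 (-0.66, SE 0.25), Add2 (-0.37, SE 0.13) and the erythroid transcription factor gene Gata1 (-0.35, SE 0.13). Of 19 megakaryocyte and platelet genes 18 were lower (median -0.221, adjusted p of 0.00129, adjusted p = 0.544 with an estimated correlation). Ppbp, a platelet chemokine gene, fell with adjustment over the list alone (-0.49, SE 0.11, list-alone adjusted p 0.0358), and Treml1 (-0.34, SE 0.09), Zfpm1 (-0.43, SE 0.14) and Thbs1 did not pass. Of 23 mast cell, basophil and eosinophil genes 20 were lower (median -0.215, adjusted p of 0.00134, adjusted p = 0.544 with an estimated correlation). Examples are the basophil protease genes Prss34 (-1.02, SE 0.33) and Mcpt8 (-0.72, SE 0.25) and the eosinophil granule gene Prg3 (-0.33, SE 0.10), and Prss34 was 9.07 in knockout-labelled array 1 against 10.51 and 10.53 in the others. Of 26 long-term stem cell genes 23 were lower (median -0.200, adjusted p of 0.00666, adjusted p = 0.544 with an estimated correlation). Fhl1 fell with adjustment over the list alone (-0.49, SE 0.10, list-alone adjusted p 0.0236), while Ndn was at -0.43 (SE 0.16), Trpc6 at -1.21 (SE 0.46) and the interferon-induced Ifitm1 at 0.55 (SE 0.16). Fhl1 lies on the X chromosome. It was 7.47, 7.61 and 7.31 in arrays 1, 2 and 3 labelled Lxn knockout, against 7.96 ± 0.07 in wild type. Trpc6 was low only in the 2 arrays with Y-linked signal (6.65 and 7.10, against 8.85 in array 2 and 8.74 ± 0.19 in wild type), at -1.87 without array 2 (adjusted p of 5.3e-05) and -0.77 without array 1. Without knockout-labelled array 1 the stem cell, megakaryocyte and mast cell lists had camera adjusted p values of 0.215, 0.160 and 0.106, with medians of -0.140, -0.137 and -0.125. Without wild-type array 2 the medians of the erythroid, megakaryocyte and stem cell lists were -0.142, -0.124 and -0.111, still passing camera (adjusted p of 0.0386, 0.0194 and 0.0376).

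**Figure D2:**
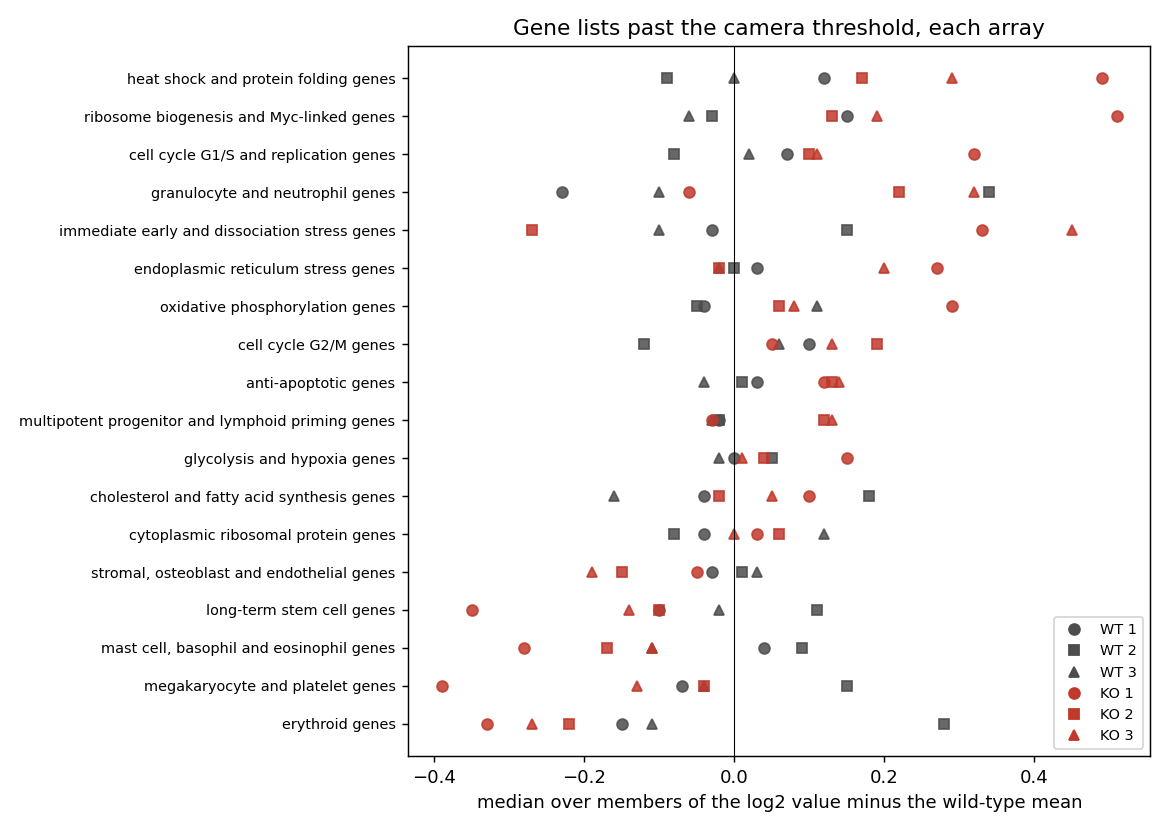
For the 18 gene lists past the camera threshold (vertical axis), the median over members of the log2 value minus the wild-type mean (horizontal axis), 1 symbol per array, grey for wild type and red for the label Lxn knockout. The ribosome biogenesis list reaches 0.51 in knockout-labelled array 1 and 0.13 in array 2, and the ribosomal protein and cholesterol lists, near 0, turned sign when the arrays were quantile-normalized again.

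Granulocyte and neutrophil genes rose (18 of 24 higher, median 0.189, camera adjusted p of 6.4e-04, adjusted p = 0.552 with an estimated correlation). Examples are the granule protease gene Ctsg (0.35, SE 0.12), Lcn2 (0.46, SE 0.17) and Chil3 (0.44, SE 0.17), and the list's median was -0.23, 0.34 and -0.10 in the wild-type arrays themselves. It was 0.069 without wild-type array 1 (camera adjusted p of 0.0480), 0.352 without wild-type array 2 and 0.101 without knockout-labelled array 3. Multipotent progenitor and lymphoid priming genes rose (15 of 25 higher, median 0.098, adjusted p of 0.0127, adjusted p = 0.544 with an estimated correlation), with the transcription factor genes Irf8 at 0.42 (SE 0.11), Satb1 at 0.24 (SE 0.09) and Tcf4 at 0.20 (SE 0.08). Monocyte, macrophage and dendritic cell genes did not pass as a list (adjusted p 0.412). With adjustment over the list alone Ccr2, Irf8 and Csf1r, the receptor of macrophage colony-stimulating factor (0.50, SE 0.14), rose and the complement gene C1qb (-0.50, SE 0.15) fell. Stromal, osteoblast and endothelial genes fell (20 of 23 lower, median -0.127, adjusted p of 0.0127, adjusted p = 0.548 with an estimated correlation), with Col1a2 at -0.33 (SE 0.10) and Alpl at -0.29 (SE 0.115). The stromal and progenitor medians lay at percentiles 23.6 and 91.5 of random lists matched on mean level. Neither list thus moved more than other genes of its brightness. The progenitor list lost its call without knockout-labelled array 2 (median 0.017, adjusted p of 0.0712) or array 3 (0.029, adjusted p of 0.113), its median was 0.158 without array 1 and 0.048 without wild-type array 2, and the stromal list without array 3 (adjusted p of 0.0594).

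The measured markers used for sorting did not differ beyond the spread between arrays. Flt3 is taken here for the receptor written as Flt2, which the series text does not settle. Kit was 12.13 ± 0.07 in wild type and 11.91 ± 0.38 in the arrays labelled Lxn knockout (-0.22, SE 0.17, adjusted p 0.502), and it was lowest in array 1 at 11.48. Flt3 (-0.03, SE 0.11) turned sign when the arrays were centred on their medians, and Cd34 (-0.01, SE 0.09) did so too. Ly6a, which encodes Sca-1, had no feature of its own in the probe table and was not analysed here. The list of sort and lineage-gate markers had a camera adjusted p of 0.274 over 12 members, with Cd48 at 0.36 (SE 0.11) and Il7r at 0.25 (SE 0.15).

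Genes that flank Lxn on chromosome 3 were examined because alleles that travel with a targeted gene can change probe binding. Of 50 measured flanking genes, 22.0% had an unadjusted p under 0.05, against 13.8% of other genes (Fisher's exact test, two-sided p 0.0993), 6 higher and 5 lower. Nmd3 was at 0.35 (SE 0.11), Trim59 at 0.52 (SE 0.18) and Kcnab1 at -0.25 (SE 0.09). Camera gave an adjusted p of 0.412 for this list. The share was 4.0% without wild-type array 2, below the 7.2% of other genes. Without knockout-labelled array 1 it was 36.0%, against 23.5% of other genes (Fisher's exact p 0.0450).

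The remaining lists did not pass camera on the deposited values. Adhesion and niche-binding genes had a median of -0.036 (adjusted p 0.561), with Thbs4 at -0.32 (SE 0.08), Vcam1 at -0.52 (SE 0.18) and Sdc4 at -0.32 (SE 0.12), and latexin and carboxypeptidase genes had a median of -0.109 (adjusted p 0.175), with Cpa5 at -0.27 (SE 0.09), Cpxm1 at -0.35 (SE 0.15) and Cpa3 at -0.63 (SE 0.32). Antioxidant and glutathione genes (adjusted p 0.0856) included the heme oxygenase gene Hmox1 at -0.67 (SE 0.18), which passed without knockout-labelled array 2 (-0.88, adjusted p of 0.0127), and the mitochondrial peroxiredoxin gene Prdx3 at 0.41 (SE 0.15). Adjusted p was 0.0702 for p53 targets, 0.0856 for B cell and plasma cell genes, 0.0930 for small nucleolar and other small RNA genes, 0.136 for Hox and cofactor genes, 0.175 for NF-kB targets, 0.233 for replication-dependent histones and 0.380 for the Notch pathway. It was 0.400 for the Wnt pathway, 0.435 for class II antigen presentation, 0.480 for quiescence genes, 0.561 for TGF-beta and BMP genes, 0.893 for T and NK cell genes and 0.932 for interferon-stimulated genes. The interferon list passed as higher without knockout-labelled array 1 (median 0.122, adjusted p of 1.3e-04) and as lower without array 2 (-0.222, adjusted p of 2.5e-04). After quantile normalization over 1 feature per gene it passed as lower (adjusted p of 0.0199), as did the adhesion list (0.0472), while over all tested features they missed the threshold (0.0512 and 0.0605). Camera compares a list with other genes, and its direction differed from the sign of the median or the mean in the monocyte, T cell, quiescence, interferon, TGF-beta and flanking-gene lists.

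Over all 39 lists, 18 passed camera with its preset correlation, 13 higher and 5 lower. With a correlation estimated from these arrays 0 passed (smallest adjusted p 0.439), with 2 at an unadjusted p under 0.05, and fry, which asks whether members move one way on balance, passed 0 (smallest adjusted p 0.377), with 3 at an unadjusted p under 0.05. Over all lists 16 members passed with adjustment over the list alone, counting repeats, and 0 over all features. The 13 higher lists had mean levels of 9.39 or more, and the 5 lower lists had mean levels of 8.43 or less. Features of the same brightness moved alike: the median change was -0.147 in the fourth decile of mean level and 0.090 in the eighth, and it was -0.020 and 0.008 after the arrays were quantile-normalized again. After that step, 8 of the 18 lists kept their call and direction: heat shock, ribosome biogenesis, G1/S and oxidative phosphorylation genes, and the lower megakaryocyte, stem cell, mast cell and erythroid genes. The medians of ribosome biogenesis, G1/S and oxidative phosphorylation genes were then 0.182, 0.108 and 0.072.

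**Figure D3:**
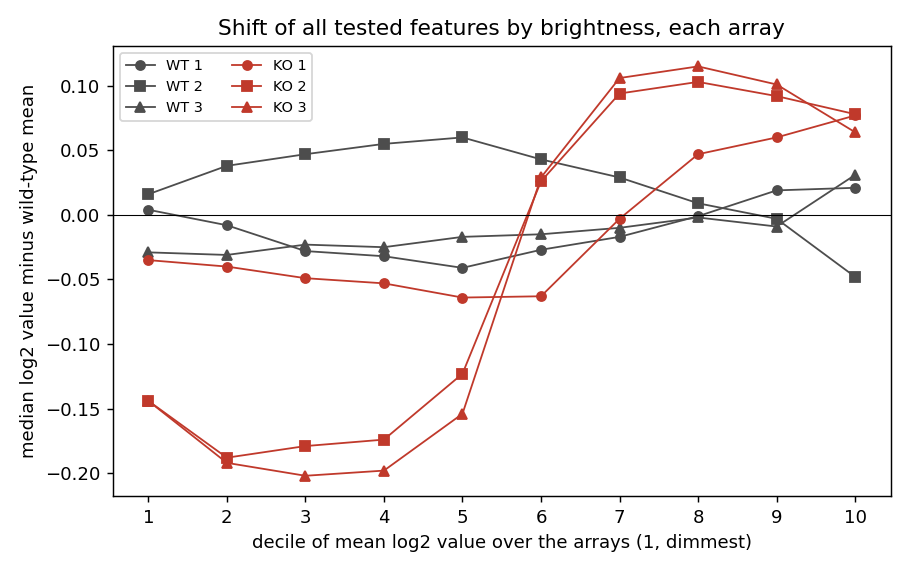
Median log2 value minus the wild-type mean (vertical axis) of all tested features in each decile of mean level (horizontal axis, 1 is dimmest), 1 line per array, grey for wild type and red for the label Lxn knockout. Knockout-labelled arrays 2 and 3 run from -0.174 and -0.198 in the fourth decile to 0.103 and 0.115 in the eighth.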

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

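The tests of the Xist level, of the position of array 2, of single arrays and of level-matched lists were chosen after the result was seen, and quantile normalization and the estimated correlation, planned as alternatives, were taken as tests of an explanation after it. The reading of array 2 was changed to open once its values were known.

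Among the 12147 features that the probe table gives no gene, which no comparison above uses, 104 were at least 1.5-fold higher in the arrays labelled Lxn knockout than in the wild-type arrays at an unadjusted p under 0.01, and 32 were lower. None passed an adjusted p of 0.05 in limma, and 1496 had an unadjusted p under 0.05. Their identity was not analysed here.

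Knockout-labelled arrays 1 and 3 stood apart from array 2 and from wild type in sex-linked genes, Thbs1, Hspa1a and other genes called without array 2. A candidate explanation is RNA from male mice despite the female label: the higher of the 2 linear Xist levels was 1.25% of the mean of the other 4 arrays, and the smallest gap of a Y-linked gene was 2.49 on the log2 scale, which leaves little room for female cells in these pools. Array 2 could also be a wild-type array: it lay past the midpoint in 10.4% of the 48 autosomal genes chosen without it. Wild-type arrays 1, 2 and 3, when left out, did so in 12.2%, 20.0% and 0.0% of the genes chosen without them. A female knockout array could lie there as well. Lxn does not decide it, at 8.53 in array 2 and 8.61 in array 3, against 8.56, 8.70 and 8.58 in wild type. The 5 genes past the midpoint in array 2 were Lrmda, Dglucy, Lgmn, Gdf3 and Card9. Lrmda, the furthest past it, was as low in array 2 as in arrays 1 and 3. The wide distribution of array 2 is shared with array 3, so this stays open. Set alone against the 3 other arrays without Y-linked signal, and assumed to vary like them, array 2 gave 3 features past the adjusted threshold and the wild-type arrays 1, 9 and 2, while at an unadjusted p under 0.05 it gave 2997, the most, and they gave 527, 2202 and 259, so these counts do not place it. Sex and genotype cannot be told apart for the genes that moved in arrays 1 and 3 alone, since no wild-type array had Y-linked signal; in 16 of the 48 genes array 2 lay inside the wild-type range.

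Called lists of bright genes rose and called lists of dim genes fell. The knockout-labelled arrays had wider distributions, with interquartile ranges of 3.017, 3.211 and 3.231 against 2.965, 2.890 and 2.958 in wild type, and normalizing the tested features to 1 distribution ended 10 of the 18 calls. In 6 of these 10 the median lay inside the central 95% of random lists matched on mean level. They were the progenitor, stromal, anti-apoptotic, G2/M, glycolysis and cholesterol lists. These 6 medians did not leave the range of other genes of their brightness, so that width may account for them. The G2/M, anti-apoptotic and progenitor medians lay high in it, at percentiles 94.9, 95.2 and 91.5. A move beyond brightness is therefore not excluded for them. In 4 the median lay outside (granulocyte, immediate early and endoplasmic reticulum genes on the side of their call, ribosomal protein genes on the other), so width alone stays open for these 4. For the 8 other lists the call remained once the arrays shared 1 distribution, and in 8 of 8 the median change lay outside that range. The second value adds little, because these lists were picked by a step that removes the same shift. The random lists also hold genes drawn 1 by 1, whose medians spread less than those of genes that vary together. Members that vary together between arrays may account for these calls, since the lowest adjusted p with an estimated correlation among them was 0.544.

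The 6 arrays make 10 splits of 3 against 3, too few for a share under 0.05. For features past the adjusted threshold the real count was 0 and the highest of the other splits 0, so 10 of 10 splits gave as many. For features at an unadjusted p under 0.01 and 1.5-fold, the real count was 44 and the highest other 123, and 4 of 10 splits gave as many. For gene lists past camera the real count was 18 and the highest other 20, and 6 of 10 splits gave as many. The split with 123 features sets wild-type arrays 1 and 3 with knockout-labelled array 2 against the rest. It keeps both arrays with Y-linked signal on 1 side, and which features make up its count was not examined. At an unadjusted p under 0.05 alone the order differs: the real split had the most features (3346, next 1880), and that split had 663.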

How the results depend on the processing

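The alternatives without knockout-labelled arrays 1 and 3, with autosomal genes only and with quantile normalization over 1 feature per gene were chosen after the result was seen. The first of these leaves 1 knockout-labelled array, which is assumed to vary like the wild-type arrays, so its counts and p values rest on the wild-type spread. Unless a reason is given, the cause of a difference was not tested. Lxn kept its direction and its side of the threshold under every alternative (-0.33 to -0.04 with single arrays left out). Over 103 genes and 1623 alternatives 1575 labels were the same, 0 weaker, 26 stronger and 22 reversed. No gene passed in the main comparison, so none could become weaker. For genes, the same label means the same direction and still not passing. Over 18 lists and 324 alternatives 230 were the same, 85 weaker, 0 stronger and 9 reversed. Only lists that had passed were followed here, so none could become stronger.

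The count of 0 features past the adjusted threshold went to 0 to 145 with single arrays left out, 145 of them without knockout-labelled array 2. Without arrays 1 and 3 it was 3, among them Lrmda at -1.66 (adjusted p 0.0480), and it stayed at 0 under every other alternative apart from the block. The count of 44 features at an unadjusted p under 0.01 and 1.5-fold went to 24 to 252 with single arrays left out. It was 28 with features above the median level, where fewer are tested, 86 with array weights, 159 with all features of the value table, where more are tested, 5 in the equal-variance two-sample test and 174 without arrays 1 and 3. The split of 23 higher and 21 lower was 39 and 11 after centring and 29 and 13 with autosomal genes, 45 and 17 without wild-type array 1 and 159 and 93 without knockout-labelled array 2, but 9 and 39 without wild-type array 2, 38 and 75 without knockout-labelled array 1, 31 and 55 with array weights and 45 and 129 without arrays 1 and 3.

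The replicate number as a block moved the count past the adjusted threshold from 0 to 1 (Lrmda, adjusted p 0.0409) and the looser count from 44 to 148. The samples share only a number: deviations of same-numbered arrays correlated at -0.01 to 0.08, and 2 of 6 arrays correlated best with their own number, so no pairing was used.

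Thbs1 ranged from -2.75 without array 2 to -1.18 with single arrays left out, and was 0.14 (adjusted p 0.823) without arrays 1 and 3. The 18 called lists became 0 with an estimated correlation, 0 with fry, 8 after quantile normalization (4 higher, 4 lower), 10 with 1 feature per gene (4 and 6), 12 with features above the median level (4 and 8, against 13 and 5) and 13 to 21 with single arrays left out. The share of Lxn-flanking genes was 14.9% within 10 Mb (Fisher's exact p 0.736), and 4.0% to 36.0% with single arrays left out. It was below the share of other genes without wild-type array 2. It passed an unadjusted p of 0.05 by Fisher's exact test without wild-type array 1 (24.0% against 11.5% of other genes, p 0.0121). The same held without knockout-labelled array 1 (36.0% against 23.5%, p 0.0450).

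These changes turned sign. Flt3 ran from -0.106 to 0.0854 and Cd34 from -0.0530 to 0.0214 with single arrays left out; centred on array medians they were 0.0273 and 0.0430, Flt3 was 0.0390 with array weights, and without arrays 1 and 3 they were 0.12 and 0.0650. Without arrays 1 and 3, Kit was 0.0191, Eif2s3y -0.0123, Kdm5d -0.17, Uty -0.19, Pgr 0.33, Trpc6 0.10, Creld2 -0.0347, Fos -0.0805, Socs3 -0.0662, Gbp4 0.70, Gbp11 0.40, Atf3 -0.55, Cxcl2 -0.46 and Gfi1b 0.0537. The cytoplasmic ribosomal protein list ran from -0.008 to 0.091 and the cholesterol and fatty acid list from -0.022 to 0.140 with single arrays left out, and they were -0.034 and -0.018 after quantile normalization, or -0.026 and -0.021 over 1 feature per gene. Without arrays 1 and 3 the cholesterol list was -0.019, the immediate early list -0.268 and the endoplasmic reticulum list -0.017.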

Other observations

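The test of neighbouring genes was planned before its result was seen, and the use of the flanking share as a test of an explanation was chosen after the result was seen, with its reading changed to open once its value was known.

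Some single genes moved with the Y-linked signal; they were chosen after their values were seen and stand for no tested group. Pgr, the progesterone receptor gene, was 9.13, 8.95 and 9.11 in wild type, 9.39 in knockout-labelled array 2, and 6.44 and 6.20 in arrays 1 and 3. The interferon-inducible guanylate-binding protein genes Gbp4 (6.45 and 7.01 in arrays 1 and 3, 9.35 in array 2) and Gbp11 (6.41 and 7.03, against 9.42 in array 2) took the same course, on chromosome 5. The list of interferon-stimulated genes, which holds Gbp4, did so in part, with medians of -0.45, 0.24 and 0.05 in arrays 1, 2 and 3. It passed camera as lower without array 2 (median -0.222, adjusted p of 2.5e-04), but array 3 alone was not low. In the other direction, the stress-response gene Atf3 (11.40 and 11.38 in arrays 1 and 3, 9.66 in array 2) and the chemokine gene Cxcl2 (9.44 and 9.57, against 8.28) were higher. Gfi1b, a transcription factor gene of erythroid and megakaryocyte cells, was 9.18 and 9.69 in arrays 1 and 3, 10.75 in array 2 and 10.60, 10.81 and 10.70 in wild type. These genes were chosen because array 2 did not go with arrays 1 and 3, so testing array 2 against wild type on them decides nothing. Array 2 alone minus wild type was 0.33 for Pgr, 0.70 for Gbp4, 0.40 for Gbp11, -0.55 for Atf3, -0.46 for Cxcl2 and 0.0537 for Gfi1b. Each of these changes ran opposite to that of arrays 1 and 3, though that of Gfi1b was small. This holds for the picked genes only. Among the 48 autosomal genes chosen without array 2, others ran the same way as arrays 1 and 3, such as Hmox1 and Tmem121b.

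Genes that differ in all 3 knockout-labelled arrays, array 2 included, could lie in DNA that differs between the 2 mouse lines. If a few inherited stretches gave rise to most of them, the 100 autosomal genes with the smallest p would be neighbours more often than chance: they held 5 pairs within 10 steps in gene order, against a mean of 6.00 and a 95th percentile of 10 over 10000 permutations (permutation p 0.717). That argues against stretches that hold several of these 100 genes within 10 steps as the source of most of them. None of the 100 passed the adjusted threshold, so many may be there by chance, and pairs further apart were not counted. They were ranked by p alone, with no need to differ in every array. Steps were counted over 16451 ranked genes, which leave out predicted genes and genes without a feature of their own. Inherited DNA as the source of single named genes therefore stays open. Synb and Entpd4 are 1 such pair, 1 step apart and both lower. Next to Lxn itself, 22.0% of genes had an unadjusted p under 0.05 against 13.8% of other genes, a difference that Fisher's exact test does not settle (p 0.0993), so carried-over DNA there stays open.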
